A study of Mus musculus with 12 samples.

How the data were processed

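RNA of 12 samples was hybridised to 1-colour Agilent mouse arrays. The samples form 4 groups of 3: control or JMJD3 knockdown neural stem cells, each with vehicle or TGFb. Per the labels' protocols, 500 ng of total RNA per sample was amplified with an oligo-dT primer and labelled with Cy3. Per the file headers, the scanner images were read with Agilent Feature Extraction 10.7.3.1 and probe positions refer to the mouse genome build mm9. The deposited scanner files give an intensity for each spot on a linear scale, and the processed signal used here is the software's background-corrected intensity, per the file headers. Each array held 43020 gene probe spots and 1377 control spots, and 399 of the 39429 distinct gene probes were printed 10 times. The authors also deposited a table of processed values, which are log2 values. In that table all 12 columns share a median of 7.93 and a lowest value of 5.66, as quantile normalization between arrays would leave them. Each of the 12 columns matched its own array best. Scale and direction follow from that match, while the authors' background correction, and any centring beyond the shared distribution, are not given in the sources used here. Of the table's 45220 entries 823 were empty.

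The arrays lie on 4 slides that were scanned on 1 day, so that scan day and slide cannot be tested apart. Slide 1 held 1 vehicle array of each line, slide 2 held 2 control arrays and 1 knockdown array of which 1 was treated with TGFb, slide 3 held all 4 groups, and slide 4 held 3 arrays with TGFb. Groups were taken from the labels. The 75th percentile of the processed signal ran from 3175 to 4462, and 70.2% (vehicle knockdown replicate 3) to 78.4% of probes were well above background. No spot was saturated (0 on each array).

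Control spots were left out, spots of 1 probe were averaged, and spots marked as outliers by the scanner software were set aside. The log2 of the processed signal was taken relative to each array's 75th percentile. Probes well above background on all 3 arrays of at least 1 group were kept (29968), and each gene was represented by its kept probe with the highest mean, which gave 24146 genes. Of these, 4853 had more than 1 kept probe. Of the probes, 26055 were named through accessions in a RefSeq table (GRCm38.p6, used for names only), 3358 of them with a changed symbol, and 13374 kept the file's name. All 348 entries of the 22 gene lists matched a probe, though not each was kept.

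Groups were compared with limma 3.58.1 in R 4.3.3 (lmFit, contrasts.fit and eBayes with a trend), in 1 fit over the 12 arrays with a mean for each group, 8 residual degrees of freedom and 3.11 prior degrees of freedom. Tests were two-sided, with Benjamini-Hochberg adjustment and a threshold of 0.05. The 5 comparisons were TGFb in each line, knockdown under each treatment, and the difference of the TGFb responses. Gene lists were tested with camera (preset correlation of 0.01), adjusted over all 110 tests of 22 lists in 5 comparisons. Of these 16 passed the threshold, and 4 did with an estimated correlation, namely the TGFb targets and the BMP targets with TGFb in each line. In 27 of the 110 tests the list's median, mean and test differed in sign, and 0 of them passed. The overall response was compared over genes chosen by the mean response of both lines, so that neither line is favoured. The mean score per array was tested over all 400 relabellings of the knockdown within each treatment. Some of these exchange the label in 1 treatment only, which adds up the knockdown's own effects on a gene set. The permutation p is therefore not exact for the difference of responses where the lines also differ apart from it. A gene not well above background on any array of 1 group has only a bound. The bound sets the bright group's mean against, on each dim array, the higher of the dim probe's own signal and the lowest signal of a probe well above background.

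The groups, tests, gene lists, alternatives and the rule for named genes were fixed before the data were examined. The rule named Kdm6b, up to 12 genes with the largest rise and 12 with the largest fall for TGFb in control cells and for knockdown without TGFb, up to 6 of each for the other comparisons of 2 groups, up to 10 of each for the difference of responses, and up to 4 members of each list. Named genes of the first kinds had non-overlapping arrays, which chance gives for 10% of genes at 3 arrays against 3, and genes known only by clone or accession names were passed over. Some genes that the rule names are not reported here. The alternatives were another background correction (normexp on the mean and background signals, with an offset), normalizations, filters, probe rules, priors, array weights, slide or replicate blocks, sample choices, thresholds, the authors' values, and each array left out.

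Arrays of different groups deviated together when they shared a slide: the correlation of their deviations from the group means was positive in 12 of 12 such pairs (median 0.36) and had a median of -0.16 across slides. Replicate numbers paired the arrays only in the comparison of knockdown and control without TGFb (0.47, 0.58 and 0.25), where the number is also the slide. With the replicate number as a block that comparison called 5869 genes. The values with slide as a block therefore stand beside the results. Within a slide a group has at most 2 arrays, so that no count of genes was made there.

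The steps were tested on simulated data of 24078 genes, with 100 genes changed 1.5-fold and 100 changed 2-fold in each comparison. The noise was drawn independently for each gene and array, with no slide effect and no other difference between the groups. The values therefore do not show how the steps behave where arrays of a slide deviate together or the lines differ in many genes. For TGFb in control cells 59% and 69% of them were recovered and 10 unchanged genes were called. For TGFb in knockdown cells these values were 54%, 74% and 3, for knockdown without TGFb 45%, 65% and 4, and for knockdown with TGFb 63%, 71% and 4. For the difference of responses they were 45%, 54% and 6. A response set to 80% of the control's was found at 80.4% over 620 genes with a permutation p of 0.08, so that the test missed the threshold at that size. Files were read with Python 3.11.15, pandas 2.3.3 and numpy 2.4.6, and figures were drawn with matplotlib 3.10.9.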

Results

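Gene expression was measured in mouse neural stem cells taken from the cerebral cortex of embryos and grown in culture. A control line stably carried an shRNA of random sequence, and a knockdown line carried an shRNA against JMJD3. JMJD3 is the protein of Kdm6b, an enzyme that removes methyl groups from lysine 27 of histone H3. Cells of each line received vehicle or transforming growth factor beta (TGFb) at 5 ng/ml for 2.5 h, and 3 samples of each of the 4 groups were hybridised to 1-colour arrays. The 75th percentile of the processed signal lay between 3175 and 4462 on the 12 arrays. Between 70.2% and 78.4% of the probes were well above background, and 0 spots were saturated. Replicates of a group correlated with r between 0.994 and 0.998 across genes, which are not independent of each other. The labels do not say that replicates came from separate cultures, so the p-values measure only the spread between these samples, which may be technical. The number of arrays limits the precision: the median standard error (SE) of a log2 change was 0.10 between 2 groups and 0.14 for a difference of TGFb responses. All values below are log2 differences between groups of 3 arrays unless a fold is given, and errors are SE of the fit. A fold given as at least some value rests on the scanner software's background correction: of 24 such bounds of named genes, 22 were not reached with normexp background correction, and 22 not with the authors' processed values.

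Kdm6b, the gene targeted by the shRNA, was lower in the knockdown line under both treatments. Its probe lies on chromosome 11 from 69212177 to 69212236 (mm9). With vehicle, its log2 signal relative to the array's 75th percentile was -1.94 ± 0.03 (SD, n = 3) in knockdown cells and -0.77 ± 0.06 (SD, n = 3) in control cells. That is a change of -1.16 ± 0.05, or 2.24-fold less (limma adjusted p = 1.1e-07). With TGFb the change was -1.40 ± 0.05, or 2.63-fold less (adjusted p = 2.8e-08). Within single slides the vehicle change lay between -1.10 and -1.22 and the change with TGFb was -1.32 and -1.47, and the 6 knockdown arrays all lay below the 6 control arrays. TGFb itself gave Kdm6b a change of 0.12 ± 0.05 in control cells (adjusted p = 0.24) and -0.11 ± 0.05 in knockdown cells (adjusted p = 0.30), neither of which passed the test.

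**Figure D1:**
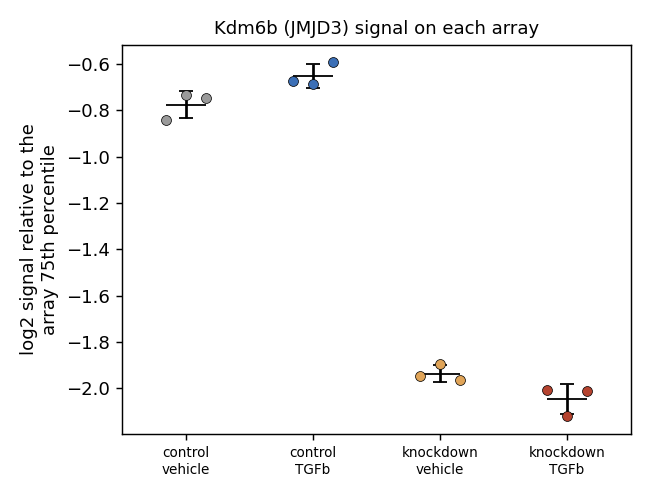
Kdm6b signal on each of the 12 arrays, as log2 relative to the array's 75th percentile, by group. Points are arrays, horizontal bars are group means and error bars are SD (n = 3), and all 6 knockdown arrays lie below all 6 control arrays.

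The first comparison asked which genes respond to TGFb within 2.5 h in control neural stem cells. Among the largest rises was that of Col2a1, a fibrillar collagen of cartilage (5.47 ± 0.10). Mep1a rose by 4.86 ± 0.11, Scx, a transcription factor of tendon progenitors, by 4.76 ± 0.16 and Trim29 by 4.59 ± 0.19. The adenylate cyclase gene Adcy7 rose by 4.15 ± 0.15, Lrrc75b by 4.03 ± 0.08, the inhibitory Smad gene Smad6 by 3.92 ± 0.11, Acox2 by 3.90 ± 0.13 and Nrip3 by 3.79 ± 0.08. The cytokine gene Il6 was not well above background in any vehicle array and rose at least 4.21-fold. The adjusted p of each of these was 1.8e-05 or lower. Trim29 was well above background on only 1 of the 3 vehicle arrays. With normexp in place of the scanner software's background correction the rises were 3.00 for Scx, 1.88 for Trim29 and 2.64 for Adcy7, and that of Il6 lay under its bound.

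Among the genes that fell with TGFb in control cells were B3galt2 (-2.31 ± 0.15), the immediate early gene Egr4 (-2.18 ± 0.14), the POU domain factor Pou3f1 (-2.15 ± 0.10), the vasodilator peptide gene Adm (-2.14 ± 0.14) and Gas1, which encodes a Hedgehog co-receptor (-1.87 ± 0.07). Other genes that fell ended below background with TGFb and have only a bound. Those of Dleu7 and the transcription factor gene Osr2 were at least 3.23-fold and 3.05-fold. The falls of Itprid1, Gjd2, the neuropeptide Y receptor gene Npy2r and Steap4 were at least 2.21-fold, 1.87-fold, 1.85-fold and 1.76-fold. With normexp background correction the value of B3galt2 was -1.26 and that of Dleu7 was -0.37, under its bound. Osr2, Itprid1, Gjd2, Npy2r, Steap4 and Spire2, another gene below background with TGFb, lost the call under it (adjusted p from 0.0689 to 0.776). Spire2 lost it with the authors' processed values too (adjusted p = 0.0852). In all, 2451 of 24146 genes passed the limma test (adjusted p under 0.05), 1311 higher and 1140 lower with TGFb, and 436 of them changed at least 2-fold, 326 higher and 110 lower. With slide as a block the count was 2905. With only changes of at least 1.5-fold it was 965, and at an adjusted p under 0.01 it was 1571.

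Of the 22 measured genes on the list of TGFb feedback regulators and early target genes, 13 rose and 3 fell with TGFb in control cells (13 and 4 adjusted over the list alone). They included Pmepa1, which restrains Smad signalling (3.78 ± 0.05), Ldlrad4 (3.00 ± 0.13) and the inhibitory Smad gene Smad7 (2.83 ± 0.18). The list as a whole rose by a mean of 1.01 (camera adjusted p = 1.05e-11, and 0.00155 with an estimated correlation), with 1.01 under slide as a block and 1.00 and 0.98 within slides. Of the 10 target genes of bone morphogenetic proteins (BMP), 8 rose and 0 fell (8 and 0 adjusted over the list alone). Their mean was 1.22 (adjusted p = 1.64e-14, and 0.00154 with an estimated correlation), and the mean was 1.23 with slide as a block and 1.23 and 1.25 within slides. Smad6 led them, with the inhibitors of neuronal differentiation Id2 (2.13 ± 0.05) and Id1 (1.51 ± 0.08) and with Atoh8 (1.43 ± 0.12). In the Notch pathway, 7 of 15 genes rose and 1 fell (9 and 2 adjusted over the list alone), with a mean of 0.42, a blocked mean of 0.43 and means of 0.45 and 0.43 within slides. Nrarp (1.14 ± 0.06), Heyl (1.10 ± 0.20), Hey1 (1.04 ± 0.05) and the receptor gene Notch1 (0.92 ± 0.08) led that list (adjusted p = 5.58e-05, but adjusted p = 0.124 with an estimated correlation), whose mean was 0.27 with the authors' processed values. Of 23 genes of extracellular matrix and matrix adhesion, 7 rose and 2 fell (10 and 2 adjusted over the list alone), with a mean of 0.18, a blocked mean of 0.17 and means of 0.17 and 0.17 within slides. Timp3 (0.83 ± 0.12), Mmp2 (0.75 ± 0.12), Thbs2 (0.67 ± 0.18) and Itgb5 (0.65 ± 0.05) rose. That call too was lost with the correlation estimated (adjusted p = 0.00631, and adjusted p = 0.565 with an estimated correlation). Heyl (0.41, adjusted p = 0.0537) and Thbs2 (0.29, adjusted p = 0.115) lost the call with normexp background correction, and Mmp2 rose by 0.44 under it.

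Genes of several other lists moved in both directions with TGFb in control cells, and these lists did not pass the camera test. Of 22 immediate early genes, 4 rose and 5 fell (4 and 6 adjusted over the list alone), among them Egr4, Myc (-1.83 ± 0.09), Ier3 (1.28 ± 0.08) and Klf2 (-1.22 ± 0.08), with a list adjusted p of 0.394. Of 17 genes for TGFb superfamily receptors and Smads, 5 rose and 4 fell (6 and 4 adjusted over the list alone). The co-receptor gene Eng (1.04 ± 0.17) and Acvr1 (0.64 ± 0.04) rose, Bmpr1b (-0.85 ± 0.07) and the type II receptor gene Tgfbr2 (-0.84 ± 0.06) fell, and the list adjusted p was 0.352. Of 20 neurogenic factors and neuronal markers, 3 rose and 6 fell (4 and 7 adjusted over the list alone, list adjusted p = 0.359). The proneural gene Neurog2 (1.60 ± 0.10) and Eomes, a marker of intermediate progenitors (1.06 ± 0.10), rose, while Insm1 (-0.96 ± 0.08) and Gadd45g (-0.95 ± 0.09) fell. In the oligodendrocyte lineage, 3 of 10 genes fell and 0 rose (3 and 0 adjusted over the list alone), namely Olig2 (-0.88 ± 0.05), Pdgfra (-0.52 ± 0.07) and Olig1 (-0.17 ± 0.05), with a list adjusted p of 0.0833. Of 18 neural stem cell and radial glia markers, 3 rose and 4 fell (3 and 5 adjusted over the list alone, list adjusted p = 0.492), among them Notch1 and Emx2 (-0.90 ± 0.08). Of 10 astrocyte markers, 3 rose and 0 fell (4 and 1 adjusted over the list alone, list adjusted p = 0.268), led by Gfap (0.93 ± 0.11). Of 10 p53 target genes, Pmaip1 rose (1.54 ± 0.06) and Bbc3 fell (-0.66 ± 0.08), with 2 and 1 adjusted over the list alone and a list adjusted p of 0.79. Of 5 measured fibroblast and meningeal markers, Col1a1 rose (1.11 ± 0.11) and Prrx1 fell (-0.41 ± 0.09), with 1 and 1 adjusted over the list alone and a list adjusted p of 0.807. No gene of the cell cycle list (0 of 21, 0 adjusted over the list alone, list adjusted p = 0.492) passed the test. Col1a1 rose by 0.69 and Gfap by 0.59 with normexp background correction, and Olig1 lost the call (adjusted p = 0.286).

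The second comparison asked which genes respond to TGFb in JMJD3 knockdown cells. Among the genes that rose most were Adcy7 (5.06 ± 0.15), Col2a1 (4.92 ± 0.10), Smad6 (4.52 ± 0.11) and Scx (4.43 ± 0.16), together with Trim29, which rose at least 20.1-fold from below background. The largest falls were those of Osr2 (-2.41 ± 0.25), the aryl hydrocarbon receptor gene Ahr (-2.24 ± 0.08), B3galt2 (-1.93 ± 0.15), the nuclear receptor gene Nr5a2 (-1.73 ± 0.10) and Adm (-1.66 ± 0.14), and Dleu7 fell at least 3.85-fold. The limma test called 2291 genes, 1144 higher and 1147 lower, but of the 400 that changed at least 2-fold 319 were higher and 81 lower, and normexp background correction gave 970 higher and 672 lower. With slide as a block the count was 1905. Only slide 3 held knockdown arrays of both treatments, so that the treatments lay largely on different slides. The block shifted the log2 changes by a median of 0.08, against a median SE of 0.10. Scaling to the array median left 1470 genes and estimated array weights gave 5319, while 824 changed at least 1.5-fold (574 higher and 250 lower) and 1391 passed an adjusted p under 0.01. Under normexp background correction the values were 3.04 for Adcy7, 2.68 for Scx, -0.89 for Osr2 and -1.11 for B3galt2. Those of Trim29 (2.13) and Dleu7 (-0.37) lay under their bounds.

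Of the TGFb feedback regulators and early targets, 12 rose and 2 fell in knockdown cells (13 and 3 adjusted over the list alone). Pmepa1 rose by 4.38 ± 0.05, Smad7 by 3.31 ± 0.18 and Ldlrad4 by 2.79 ± 0.13. The mean of the list was 1.17, the blocked mean 1.18 and the mean within slide 3 was 1.24 (camera adjusted p = 5.82e-13, and 0.00154 with an estimated correlation). Of the BMP targets, 6 rose and 0 fell (6 and 0 adjusted over the list alone), with Id2 at 2.12 ± 0.05 and a list mean of 1.05, or 1.06 with slide as a block and 1.02 within slide 3 (adjusted p = 9.94e-08, and 0.00743 with an estimated correlation). In the Notch pathway 7 genes rose and 1 fell (8 and 2 adjusted over the list alone), led by Heyl (1.91 ± 0.20, but 0.78 with normexp background correction) and Nrarp (1.70 ± 0.06). Its mean was 0.47, with 0.47 under the block and 0.46 within slide 3 (adjusted p = 9.83e-06, but adjusted p = 0.0978 with an estimated correlation). The matrix list, with 5 genes up and 1 down (5 and 1 adjusted over the list alone), had an adjusted p of 0.173 in knockdown cells.

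The question named by the series is whether TGFb responsive genes need JMJD3, and it was put to the data as the difference between the responses of the 2 lines. The shRNA lines responded to TGFb with largely overlapping gene sets. Of the genes higher with TGFb, 940 were called in both lines, where 62.1 would be expected of independent lists, and of the lower genes 724, where 54.2 would be expected. The 2 responses come from separate arrays and share no control samples. They do share slides, and arrays of 1 slide deviated together, so that a slide effect can raise the overlap and the correlation. Neither was computed with slide as a block. Across all genes, which are not independent replicates, the responses correlated with r = 0.716. Across the 3793 genes that passed the test for the mean response of both lines r was 0.943, but choosing genes by that mean itself raises the correlation. Over the 3793 genes the mean response, with each gene's sign turned so that its mean response is positive, was 0.53 in control cells and 0.50 in knockdown cells. The difference was -0.03 (95% interval -0.06 to 0.00164), so that the knockdown response was 94.4% of the control response. A permutation test over all relabellings of the knockdown within each treatment gave a two-sided p of 0.06 (0.18 adjusted over the 6 gene sets tested). The smallest p the 400 relabellings allow is 0.005, and with slide as a block the difference was -0.02 with a p of 0.23. Relabellings that exchange the label in 1 treatment only add up the knockdown's own effects, which can make the p too large. For these genes, with signs turned, those effects were 0.01 without TGFb and -0.02 with TGFb. The permutation p went under 0.05 without vehicle control replicate 1 (p = 0.04), without vehicle control replicate 2 (p = 0.005) and without TGFb control replicate 2 (p = 0.04). Without TGFb knockdown replicate 1 the difference was 0.00569 (permutation p = 0.865), on the other side of 0. Under estimated array weights it was 0.00482 (p = 0.9), and with the authors' processed values it was -0.02 (p = 0.04).

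Genes that TGFb changed at least 2-fold were also compared by direction. The 328 genes that rose had mean responses of 1.79 in control and 1.76 in knockdown cells, a difference of -0.02 (95% interval -0.15 to 0.11, permutation p = 0.835, 0.835 adjusted over the sets). The knockdown's own effect on these 328 genes was -0.17 without TGFb and -0.19 with TGFb, which can make that p too large. The 98 genes that fell had mean responses of 1.43 and 1.22, a difference of -0.22 (95% interval -0.38 to -0.05), or 84.9% of the control response, with 71 of the 98 responding less in knockdown cells. The permutation p of 0.015 for these 98 genes became 0.09 once adjusted over the 6 sets, which misses the threshold. For all 426 genes the difference was -0.07 (permutation p = 0.49, 0.588 adjusted). For the 1735 genes that rose by any size it was -0.04 (permutation p = 0.39, 0.588 adjusted), and for the 2058 that fell it was -0.02 (p = 0.48, 0.588 adjusted). These sets by size and direction were not compared with slide as a block.

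**Figure D2:**
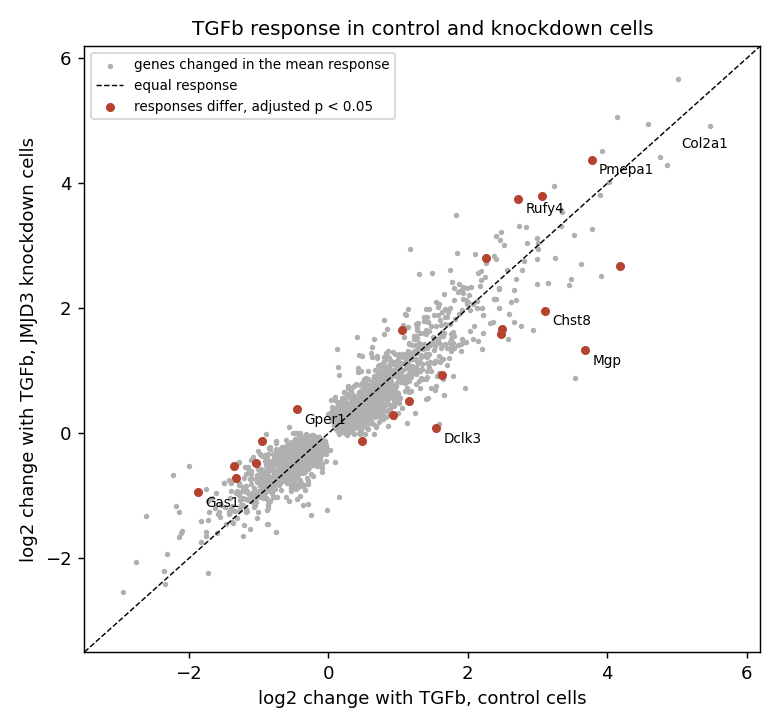
Log2 change with TGFb in JMJD3 knockdown cells (vertical) against control cells (horizontal) for the 3793 genes that passed the test for the mean response of both lines (grey), with the 21 genes whose responses differed in red. The dashed line marks equal responses. The 3793 genes were chosen by their mean response, which itself raises their correlation, and across all genes r was 0.716.

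Gene by gene, the response to TGFb differed between the lines for 21 genes, 11 with a higher and 10 with a lower value in knockdown cells. Mgp, which encodes matrix Gla protein, an inhibitor of calcification, rose by 3.69 in control and 1.33 in knockdown cells, a difference of -2.35 ± 0.21 (limma adjusted p = 0.0026). That call was lost with normexp background correction (-0.50 ± 0.12, adjusted p = 0.333) and with the authors' processed values (-0.58 ± 0.11, adjusted p = 0.12). Dclk3 rose by 1.55 in control cells and had a value of 0.09 (adjusted p = 0.64) in knockdown cells, a difference of -1.46 ± 0.13 (adjusted p = 0.0026). The sulfotransferase gene Chst8 rose by 3.11 and 1.96 (difference -1.15 ± 0.12, adjusted p = 0.007). Differences of the same sign were found for Diras2 (-0.89), Cdkl4 (-0.83), the connective tissue growth factor gene Ccn2 (-0.69), B4galt1 (-0.65), Adra2a (-0.64) and the ephrin gene Efnb2 (-0.60). In the other direction, Rufy4 rose by 2.73 in control and 3.76 in knockdown cells (difference 1.03 ± 0.15), Pmepa1 differed by 0.60 ± 0.08, Zbed5 by 0.60 and Camk2n1 by 0.54. For Gas1 (0.93 ± 0.11), Wnt5a (0.83 ± 0.10), Palmd (0.61) and Ehd4 (0.56) the positive difference stands for a smaller fall in knockdown cells. Insm1 differed by 0.83 ± 0.11, with a fall of its log2 signal in control cells (-0.96) and a value of -0.12 (adjusted p = 0.45) in knockdown cells. Gper1, which encodes a G protein-coupled receptor, fell by 0.45 in control cells and rose by 0.39 in knockdown cells. TGFb changed 17 of the 21 genes in both lines in the same direction, 3 in control cells only and Gper1 in opposite directions.

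All 21 genes were well above background on the 12 arrays and kept an adjusted p under 0.05 with slide as a block. Within slide 3, the only slide that holds all 4 groups, the differences of Mgp, Dclk3 and Chst8 were -1.84, -1.51 and -0.88. The count itself was unstable. It was 4 without vehicle control replicate 3, 13 without TGFb control replicate 1, 13 without TGFb control replicate 2, 6 without TGFb control replicate 3, 8 without vehicle knockdown replicate 2, 11 without vehicle knockdown replicate 3, 7 without TGFb knockdown replicate 2 and 4 without TGFb knockdown replicate 3. Mgp, Dclk3 and Chst8 passed the test with any 1 of the 12 arrays left out. By contrast, Zbed5 passed in 0 of these 12 fits, and Diras2, Adra2a and Gper1 each passed in 1. Over the 12 other settings B4galt1 passed in 8, with an adjusted p of up to 0.968. With normexp background correction 19 of the 21 values stayed within 1.5 times the reported ones and 13 of the 21 genes passed the test, Dclk3 (-1.31) and Chst8 (-0.97) among them, while Mgp, Diras2, Adra2a, Camk2n1, Zbed5, Palmd and Gper1 were among those that did not. The count was 45 with slide as a fixed block, 95 with slide as a random block, 95 with estimated array weights, 7 after median scaling and 4 at an adjusted p under 0.01. The authors' processed values gave 15 genes, 6 higher and 9 lower. An unadjusted p under 0.05 was reached by 1233 of 24146 genes. That is close to the share of 0.05 reached where no response differs, so the count is no sign of further genes.

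**Figure D3:**
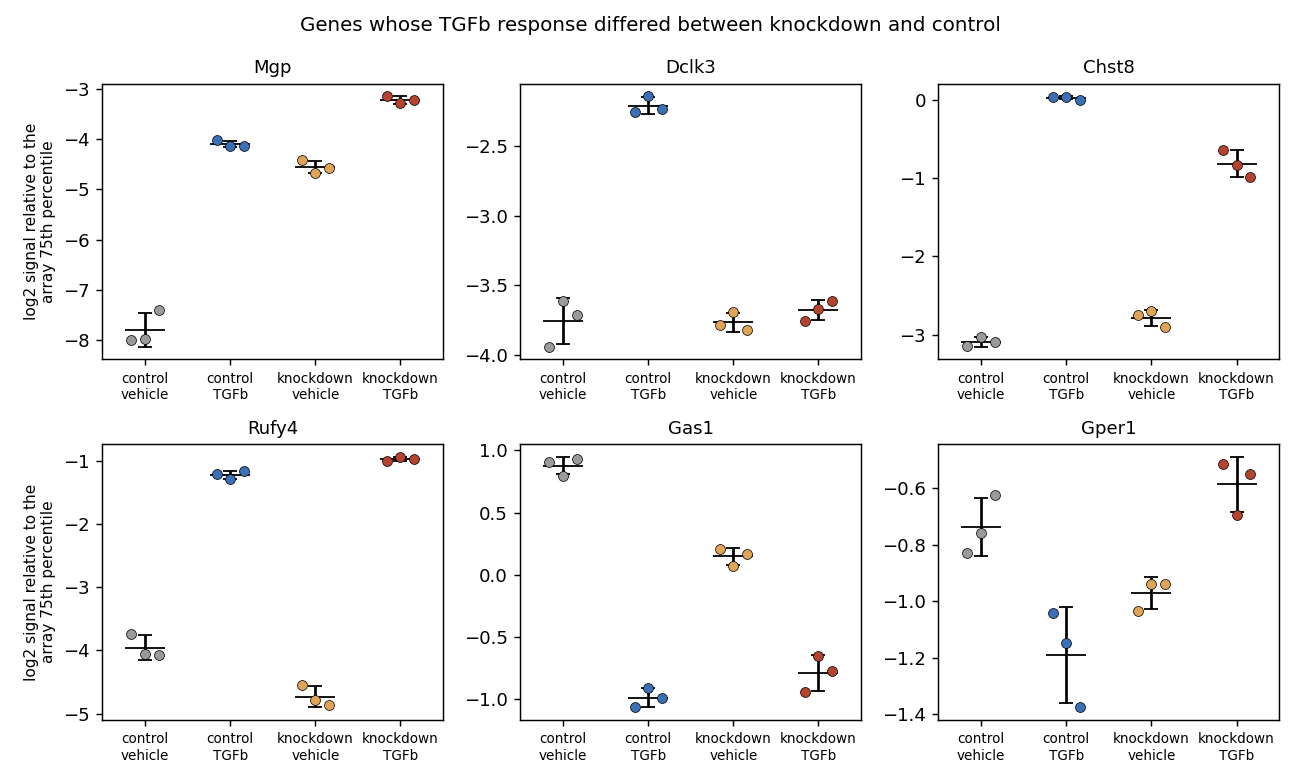
Log2 signal relative to the array's 75th percentile on each of the 12 arrays for 3 genes with a negative and 3 with a positive difference of TGFb responses. Points are arrays, horizontal bars are group means and error bars are SD (n = 3), and the differences run from -2.35 (Mgp, but -0.50 with normexp background correction) to 1.03 (Rufy4).

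Among the gene lists, the TGFb feedback regulators and early targets had a higher mean log2 change with TGFb in knockdown cells, by 0.16 (0.17 with slide as a block, 0.26 within slide 3, 0.08 with the authors' processed values). The mean keeps each gene's sign: 13 members rose and 3 fell in control cells, and 12 rose and 2 fell in knockdown cells. Pmepa1 was higher and Ccn2 lower (4 higher and 1 lower adjusted over the list alone), and the camera adjusted p was 0.0187, which became adjusted p = 0.13 with an estimated correlation. The Notch pathway had a mean difference of 0.05, a blocked one of 0.04, 0.03 within slide 3, 0.02 after median scaling and 0.11 with the authors' processed values (adjusted p = 0.0187, but adjusted p = 0.389 with an estimated correlation), with 0 genes called and 2 higher and 1 lower adjusted over the list alone. Its smallest p belonged to Nrarp (0.57 ± 0.09, adjusted p = 0.054). The BMP targets had a lower mean log2 change with TGFb in knockdown cells, with a mean difference of -0.17, a blocked one of -0.17, -0.23 within slide 3 and 0 genes called (1 higher and 3 lower adjusted over the list alone). The smallest p among them was that of Id3 (-0.66 ± 0.12, adjusted p = 0.082), and the list adjusted p of 0.0342 became adjusted p = 0.224 with an estimated correlation. Knockdown against control, the BMP list had a mean of 0.11 without TGFb (4 higher, 1 lower) and -0.06 with TGFb (2 higher, 3 lower). Neither passed the camera test (adjusted p = 0.29 and 0.909), and most of the difference of responses lay in the untreated cells. Unfolded protein and amino acid stress genes had a mean difference of -0.18, a blocked one of -0.20 and -0.33 within slide 3, with 0 genes called (0 adjusted over the list alone, adjusted p = 0.0342, but adjusted p = 0.599 with an estimated correlation). None of these 4 list differences held with an estimated correlation.

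The third comparison asked what the JMJD3 knockdown line differed in without TGFb. The largest rises in knockdown cells were those of the sialyltransferase gene St6galnac5 (3.35 ± 0.10), Mgp (3.23 ± 0.15), the neural repressor gene Scrt1 (2.50 ± 0.11), Ankrd34c (2.39 ± 0.10), the neuronal transcription factor gene Myt1l (2.38 ± 0.14), the glutathione-degrading enzyme gene Chac1 (2.27 ± 0.18), Atcay (2.26 ± 0.18), Smco3 (2.11 ± 0.25) and Trib3, a pseudokinase of the stress response (2.03 ± 0.18). The cytokine receptor gene Il20ra, the nucleotide receptor gene P2ry14 and Dmrtc1a were not well above background in control cells and rose at least 5.35-fold, 3.79-fold and 1.83-fold. The largest falls were those of Rnf43, a ubiquitin ligase that removes Wnt receptors (-3.35 ± 0.21), the complement regulator gene Cd55 (-2.63 ± 0.19), Ces2e (-2.61 ± 0.14), Slc35f3 (-2.40 ± 0.10), Cpz (-2.26 ± 0.15), Syt13 (-2.12 ± 0.22) and Rph3al (-2.03 ± 0.17). Pitpnm3, Hils1 and Prickle3 ended below background and fell at least 2.33-fold, 2.10-fold and 1.54-fold. The cholesterol transporter gene Abcg1 and Prelp also fell to below background (adjusted p = 4.6e-05 and 0.0017). Rnf43 and Cd55 were well above background on only 1 of the 3 knockdown arrays, Rph3al and Dmrtc1a on 2 of them, and Atcay and Abcg1 on 2 of the 3 control arrays. The limma test called 6722 genes, 3020 higher and 3702 lower, most of them with small changes: 460 reached 2-fold and the median absolute change was 0.38. Slides 1 to 3 each held 1 array of each line, so that slide as a block leaves these changes as they are and alters only their error, and with it the count was 9080. The changes within the 3 slides, taken in pairs of slides, correlated across all genes with r = 0.663, 0.547 and 0.618, genes not being independent replicates. At 2-fold the excess lay on the other side, with 285 higher and 175 lower. The excess of lower genes was also lost with median scaling, which left 4344 genes (2217 higher and 2127 lower), and with the authors' processed values (2593 higher and 2575 lower), while 1674 genes changed at least 1.5-fold and 4360 passed an adjusted p under 0.01. Under normexp background correction the values were 1.17 for Mgp, 1.42 for Myt1l, 0.55 for Atcay, 0.73 for Smco3, -1.19 for Rnf43, -0.83 for Cd55, -1.11 for Ces2e, -1.50 for Cpz and -0.76 for Rph3al, and Prickle3 lost the call (adjusted p = 0.202). Those of Il20ra (0.64), P2ry14 (0.44), Dmrtc1a (0.28), Pitpnm3 (-0.46) and Hils1 (-0.33) lay under their bounds.

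Without TGFb, 10 of the 22 TGFb feedback regulators and early targets were lower in knockdown cells and 0 were higher (10 and 0 adjusted over the list alone). Ldlrad4 fell by 1.22, the repressor gene Snai1 by 0.91, the matrix protein gene Tgfbi by 0.79 and Tgif1 by 0.57. The mean of the list was -0.29, with -0.29 under slide as a block and -0.28, -0.26 and -0.33 within slides (camera adjusted p = 0.0187, but adjusted p = 0.13 with an estimated correlation). With the authors' processed values 5 genes were lower and 1 higher, with a mean of -0.19, and Snai1 lost the call with them (-0.20, adjusted p = 0.0604) and with normexp background correction (-0.24, adjusted p = 0.069). Unfolded protein and amino acid stress genes were higher, with 7 of 12 up and 2 down (7 and 2 adjusted over the list alone). Besides Chac1 and Trib3, the stress factor Atf3 (1.37 ± 0.14) and Herpud1, a gene of protein degradation at the endoplasmic reticulum (1.03 ± 0.11), rose. The list mean was 0.62, its blocked mean 0.62 and its means within slides 0.70, 0.43 and 0.73 (adjusted p = 0.0187, but adjusted p = 0.565 with an estimated correlation). The 16 cytosolic ribosomal protein genes had a mean of -0.17 (blocked -0.17, and -0.16, -0.23 and -0.13 within slides) with 0 up and 1 down (0 adjusted over the list alone). That shift passed the camera test (adjusted p = 0.0286, but adjusted p = 0.667 with an estimated correlation) and was -0.04 after quantile normalization, with 1 gene up and 0 down, and -0.05 with the authors' processed values, with 0 called, but -0.16 after median scaling, also with 0 called. Of 12 interferon response genes 4 rose and 0 fell (4 and 0 adjusted over the list alone), namely Oasl2 (1.69 ± 0.35), Ifit3 (1.17 ± 0.17), Ifi44 (1.00 ± 0.27) and Isg15 (0.31 ± 0.09). This list missed the threshold (adjusted p = 0.0669). Oasl2 (0.10, adjusted p = 0.625) and Ifi44 (0.13, adjusted p = 0.416) lost the call with normexp background correction, and Ifit3 rose by 0.46.

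Markers of neural cell types moved in both directions in the knockdown line without TGFb. Among the stem cell and radial glia markers 6 rose and 5 fell (6 and 6 adjusted over the list alone, list adjusted p = 0.608), with rises of Hes5 (0.78 ± 0.11), Sox2 (0.74 ± 0.04), Slc1a3 (0.68 ± 0.04) and Sox21 (0.60 ± 0.07). Among neurogenic factors and neuronal markers 5 rose and 4 fell (6 and 4 adjusted over the list alone, list adjusted p = 0.601). The RNA-binding protein gene Elavl3 (1.26 ± 0.06) and the microtubule protein gene Dcx (1.13 ± 0.21) rose, and Insm1 (-1.72 ± 0.08) and Bcl11b (-0.92 ± 0.11) fell. Pdgfra, a marker of oligodendrocyte precursors, fell by 1.97, and of that lineage's 10 markers 1 rose and 3 fell (1 and 3 adjusted over the list alone, list adjusted p = 0.909). Apoe (1.16 ± 0.09) and Gfap (0.98 ± 0.11) rose among the astrocyte markers, of which 3 rose and 2 fell (3 and 2 adjusted over the list alone, list adjusted p = 0.492). Of 6 measured microglia and macrophage markers and 7 endothelial markers 0 were called (0 adjusted over the list alone, list adjusted p = 0.785 and 0.785). The smallest adjusted p belonged to Cx3cr1 (0.27 ± 0.27, adjusted p = 0.57) and Emcn (-0.27 ± 0.11, adjusted p = 0.11). Of the 5 fibroblast and meningeal markers, Foxc1 rose (0.33 ± 0.07) and Col1a1 fell (-0.48 ± 0.11), with 2 and 1 adjusted over the list alone and a list adjusted p of 0.659. Dcx rose by 0.39 and Gfap by 0.57 with normexp background correction, and Col1a1 lost the call (adjusted p = 0.065).

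Chromatin and signalling lists also held changes in the knockdown line without passing the camera test. Among 17 measured genes of the histone H3 lysine 27 methylation machinery, 2 rose and 4 fell (2 and 5 adjusted over the list alone, list adjusted p = 0.48), and the methyltransferase gene Ezh1 fell by 0.95. Of 15 measured Polycomb-bound developmental regulators 3 rose and 2 fell (3 and 2 adjusted over the list alone, list adjusted p = 0.728), with Tbx3 at -0.78 ± 0.07 and Hoxa2 at 0.47 ± 0.11 (0.16, adjusted p = 0.118, with normexp background correction). The remaining 10 listed regulators had no kept probe. Of 12 Wnt target genes and antagonists 4 rose and 3 fell (5 and 3 adjusted over the list alone, list adjusted p = 0.48), with rises of Wif1 (1.63 ± 0.14, but 0.98 with normexp background correction) and Sfrp2 (1.03 ± 0.06) and falls of Ccnd1 (-0.79 ± 0.05) and Sfrp1 (-0.79 ± 0.06). Of 13 contractile and mesenchymal transition genes 2 rose and 5 fell (2 and 5 adjusted over the list alone, list adjusted p = 0.48), among them Myl9 (-1.21 ± 0.06) and Actn1 (-0.96 ± 0.10). Of the matrix genes 7 rose and 7 fell (8 and 8 adjusted over the list alone, list adjusted p = 0.785), with Spp1 (1.01 ± 0.07) and Col6a1 (-0.69 ± 0.06) in opposite directions. Of the p53 targets 2 rose and 3 fell (2 and 5 adjusted over the list alone, list adjusted p = 0.659), and of the cell cycle genes 3 rose and 3 fell (3 and 3 adjusted over the list alone, list adjusted p = 0.944), led by Ccne1 (0.60 ± 0.05). Of the immediate early genes 5 rose and 7 fell (7 and 8 adjusted over the list alone, list adjusted p = 0.785), with Egr4 at -1.42 ± 0.14 and Egr1 at -1.12 ± 0.17.

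The fourth comparison set knockdown against control cells after TGFb. St6galnac5 (3.11 ± 0.10), Smco3 (2.50 ± 0.25), Ankrd34c (2.27 ± 0.10) and Myt1l (2.11 ± 0.14) rose, and Slc35f3 (-2.44 ± 0.10), Rnf43 (-2.55 ± 0.21) and Ces2e (-2.30 ± 0.14) fell, as they did without TGFb. Cd55 fell at least 6.57-fold, Ctla2a at least 2.98-fold and Fam169b at least 2.63-fold, and the metabolic hormone gene Fgf21 and Dmrtc1a rose at least 2.49-fold and 1.75-fold. With normexp background correction the values were 0.65 for Smco3, 1.28 for Myt1l, -0.74 for Rnf43 and -1.04 for Ces2e, and Fam169b, Fgf21 and Dmrtc1a lost the call (adjusted p from 0.0555 to 0.161). Under it the values of Cd55 (-0.78) and Ctla2a (-0.35) lay under their bounds. Smco3 was well above background on 1 of the 3 control arrays and Rnf43 on 1 of the 3 knockdown arrays. Between the 2 treatments, 2333 genes were higher in knockdown cells under both (363 expected of independent lists) and 2866 were lower under both (628 expected), and the changes correlated with r = 0.743 across all genes. In all 6998 genes were called, 2902 higher and 4096 lower, but of the 453 that reached 2-fold 285 were higher and 168 lower. The count was 8939 with slide as a block and 10633 with estimated array weights, and 1688 changed at least 1.5-fold (924 higher and 764 lower) and 4568 passed an adjusted p under 0.01.

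With TGFb present, 6 of 15 Notch pathway genes were higher in knockdown cells and 0 lower (6 and 0 adjusted over the list alone), among them Heyl (0.77 ± 0.20), Notch3 (0.74 ± 0.06), Hes5 (0.64 ± 0.11) and Nrarp (0.57 ± 0.06). The mean was 0.26, the blocked mean 0.24 and the means within slides 0.27 and 0.22 (camera adjusted p = 0.0187, but adjusted p = 0.389 with an estimated correlation). Without TGFb the Notch list was similar, with 5 genes higher and 1 lower in knockdown cells and a mean of 0.20, but missed the threshold (camera adjusted p = 0.389). Among TGFb superfamily receptors and Smads 5 of 17 were higher and 0 lower (5 and 0 adjusted over the list alone), led by Bmpr1b (1.00 ± 0.07) and Tgfbr3 (0.79 ± 0.12). Their mean was 0.18, the blocked mean 0.17 and the means within slides 0.13 and 0.19 (adjusted p = 0.0361, but adjusted p = 0.293 with an estimated correlation). This list too was similar without TGFb, with 5 higher and 1 lower and a mean of 0.16 (camera adjusted p = 0.0881). The TGFb feedback regulators and early targets, with 2 higher and 5 lower (3 and 5 adjusted over the list alone), had a mean of -0.13 and did not pass (adjusted p = 0.422). Ldlrad4 (-1.43 ± 0.13) and Ccn2 (-0.55 ± 0.07) were lower. Of the stress genes 6 were higher and 3 lower (7 and 3 adjusted over the list alone, list adjusted p = 0.131), with Chac1 at 1.82 ± 0.18 and Trib3 at 1.64 ± 0.18. Of the interferon response genes 5 were higher and 0 lower (5 and 0 adjusted over the list alone, list adjusted p = 0.116), led by Ifit3 (1.11 ± 0.17). Heyl lost the call with normexp background correction (0.32, adjusted p = 0.0746), where Tgfbr3 rose by 0.47, Ifit3 by 0.35 and 3 of the interferon response genes were higher.

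**Figure D4:**
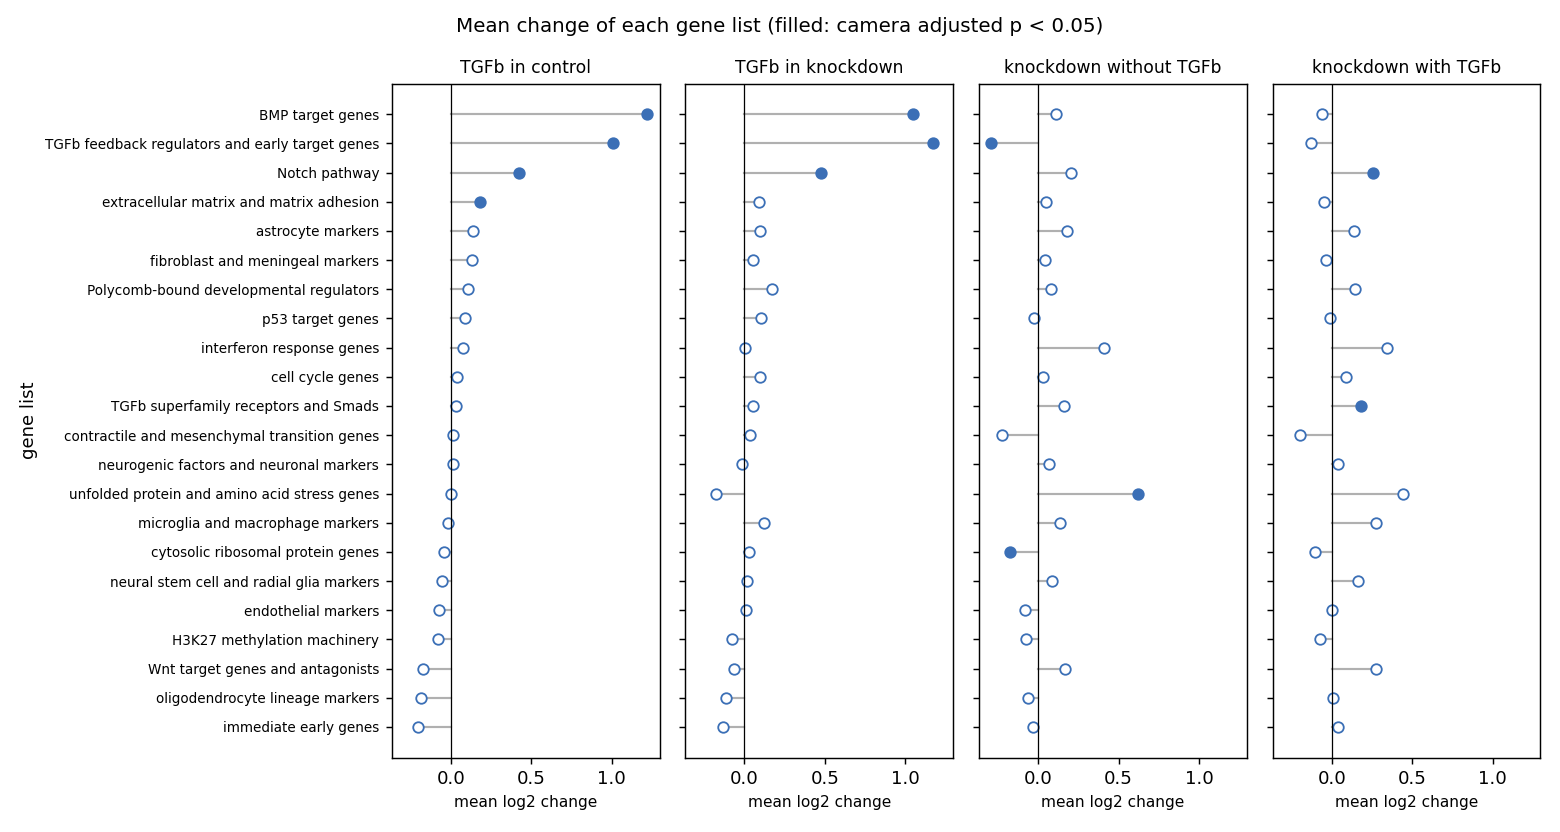
Mean log2 change of each of the 22 gene lists in the 4 comparisons of 2 groups. Each point is a list, grey lines run from 0, and filled points passed the camera test with its preset correlation, which with an estimated correlation held only for the TGFb and BMP target lists under TGFb.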

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

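The fits with slide as a block were planned, while their use as a test of a slide effect, and the tests of the list and of all genes within slides, of other TGFb responsive genes, of the interferon response genes and of the background of Mgp, were chosen only after the results they bear on were seen.

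The TGFb response of 21 genes differed between knockdown and control cells by the test of the difference itself, and with normexp background correction 13 of the 21 passed it. Among the 21, the log2 differences were -2.35 for Mgp, -1.46 for Dclk3, -1.15 for Chst8, -0.89 for Diras2, -0.83 for Cdkl4, -0.69 for Ccn2, -0.65 for B4galt1, -0.64 for Adra2a and -0.60 for Efnb2. They were 0.54 for Camk2n1, 0.56 for Ehd4, 0.60 for Pmepa1, 0.60 for Zbed5, 0.61 for Palmd, 0.73 for AW742560, 0.83 for Wnt5a, 0.83 for Insm1, 0.84 for Gper1, 0.93 for Gas1 and 1.03 for Rufy4. AW742560, known only by a clone name and so passed over in the report, rose by 3.06 in control and 3.79 in knockdown cells.

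For these 21 genes a shared slide does not account for the differences, since 21 of 21 stayed past the threshold with slide as a block. By the level fixed in advance, signal near background was argued against for the set, since 0 of 21 were under that level on any array. That level cannot exclude it, since Mgp lay above it too. With normexp 19 of the 21 differences stayed within 1.5 times the reported ones and 13 passed the test. For Mgp the background stays open, since its difference of -2.35 ± 0.21 became -0.50 ± 0.12 (adjusted p = 0.333) with normexp: the difference itself shrank, by a correction that draws dim values together whatever sets them apart. Of 100 drawn relabellings of the knockdown within each treatment (of 200), 4 gave at least 21 genes, the real one included, a share under 0.05, while the highest other gave 9595. That relabelling exchanges the knockdown label in 1 treatment only and so adds the effects of the knockdown up, and the next 2 highest, with 1491 and 1083 genes, set the TGFb arrays of slide 4 against those of the other slides, which points to a structure of the samples by slide, and 45 genes were called with slide as a block. All relabellings but that one and the real one mix the 2 lines in at least 1 treatment, which widens the spread. The share of 4 in 100 is therefore no measure of how many genes chance would call. An effect of JMJD3 on the response of these genes, and a difference between the lines from any other origin, both stay open because each line carries a single shRNA construct.

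Without TGFb the early target genes of TGFb were lower in knockdown cells (camera adjusted p = 0.0187, but adjusted p = 0.13 with an estimated correlation). A slide effect was argued against, since the highest of the list's means within the 3 slides was -0.26. Lower TGFb signalling before treatment stays open: 319 genes outside the list that TGFb raised at least 2-fold had a mean of -0.16 ± 0.05 (SE between arrays), with 106 called lower and 55 called higher, but they were as low with TGFb present (-0.19 ± 0.03), so that the shift does not belong to the untreated cells alone. The 97 genes that TGFb lowered at least 2-fold, which lower signalling would leave higher, had a similar mean of -0.17 ± 0.06 without TGFb, with 28 called lower and 23 called higher. Unlike the raised genes, these 97 had a mean of 0.05 ± 0.04 with TGFb present. With the authors' values both sets had a mean of -0.08 without TGFb. Untested and open is a direct effect of JMJD3 on some of these genes.

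A difference between the lines without TGFb was called for 6722 of 24146 genes (27.8%). A slide shift shared by both lines cancels within slides 1 to 3 by design, so that the test could not come out for one. The changes within these slides, each from separate arrays, correlated across all genes, which are not independent, with r of at least 0.547. The difference between the lines thus recurred across the slides. An interferon response to the shRNA as a part of it stays open, since 4 of 12 listed genes rose, a number between the bounds set for and against it, while 3 rose after median scaling or with the authors' values and 2 with normexp, which lie within the bound against it. Off-target effects of the shRNA and differences that arose between the 2 lines were not tested and stay open, as does an effect of JMJD3.

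In the 4 comparisons of 2 groups, 1 of 10 splits of the 6 arrays, the real one, gave as many genes as reported. These splits are too few for a share under 0.05. The real values were 2451, 2291, 6722 and 6998 genes, and the highest of the other splits gave 0 in each. Each other split mixes the 2 groups on both sides, so that any difference between them widens the spread. The 0 is therefore no measure of how many genes chance would call.

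Of the gene lists, 4 differed between the lines in their TGFb response, by means of -0.17 for BMP targets, 0.0539 for the Notch pathway, 0.16 for TGFb feedback regulators and early targets and -0.18 for unfolded protein and amino acid stress genes. None of these held with an estimated correlation.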

How the results depend on the processing

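All settings here were planned. The scan day as a block was not run, because all arrays were scanned on 1 day. Over 410 values of 210 named genes, 10144 checks under 25 settings left 9527 on the same side of the threshold, 573 lost the call and 33 gained it. In 11 checks a value called in neither fit turned its sign with a shift of at least 1 SE. In 0 checks did the sign turn where either fit called the gene. Uncalled values that turned their sign by under 1 SE count among the 9527. Sizes of dim genes depended on the background correction: of 346 called values, 90 shrank by over 1.5 times with normexp (52 calls lost) and 93 with the authors' values (38 lost), and 0 grew by as much. Under the settings not listed here, counts stayed within 1.5 times the reported one. Median scaling gave 1470 genes for TGFb in knockdown, 4344 for knockdown without TGFb and 7 for the difference of responses. Array weights gave 5319 for TGFb in knockdown, 10633 for knockdown with TGFb, 95 for the difference of responses and a mean response difference of 0.00482 (permutation p = 0.9). Slide as a fixed block gave 45 differing genes and as a random block 95. The cause of these shifts was not tested. Requiring at least 1.5-fold left 965, 824, 1674 and 1688 genes in the 4 comparisons of 2 groups, and an adjusted p under 0.01 left 1571, 1391, 4360, 4568 and, for the difference, 4, since both settings only narrow the reported sets. With the authors' values the mean response difference was -0.0226 (permutation p = 0.04), the cause of which was not tested.

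With the replicate block, counts were 2060, 1871, 5869 and 6151 in the comparisons of 2 groups and 11 for the difference of responses, and the response difference was -0.03 (permutation p = 0.13). The replicate number paired the arrays only for knockdown without TGFb, so that the 11 is not read as a weaker effect.

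Leaving out 1 array at a time gave 1833 to 2489 genes for TGFb in control, 1613 to 2422 for TGFb in knockdown, 5204 to 6961 for knockdown without TGFb, 5393 to 7157 for knockdown with TGFb and 4 to 27 for the difference of responses. The mean response difference ran from -0.0504 to 0.00569. Signal over background limits the dim genes: only 21757 of 24146 genes had a probe well above background on all 12 arrays, and genes not well above background in 1 group have bounds in place of folds. Of 24 such bounds 22 were not reached with normexp, nor 22 with the authors' values.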

Other observations

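The families by symbol and the members shown here were chosen after the data were seen.

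Gene families were formed from the opening letters of the symbols (206 families of 10 to 150 genes, 1030 camera tests, 21 past an adjusted p of 0.05 with the preset correlation and 0 with an estimated correlation). The clustered protocadherin genes of the beta group on chromosome 18, cell adhesion genes of neurons, stood out. Of 22 measured, 11 rose and 0 fell in knockdown cells without TGFb, by a mean of 0.39 (adjusted p = 2.47e-05, but adjusted p = 0.934 with an estimated correlation), and 13 rose and 0 fell with TGFb, also by a mean of 0.39. Pcdhb9 (0.80 ± 0.18), Pcdhb10 (0.77 ± 0.07) and Pcdhb15 (0.68 ± 0.09) led them without TGFb. The mean was 0.30, 0.48 and 0.39 within slides 1 to 3, and it stayed above 0 under quantile normalization (0.38), median scaling (0.40) and the authors' values (0.27). Members of this family are similar in sequence, so that probes can share signal and the members are not independent of each other. The alpha and gamma groups on chromosome 18 were too small to form a family. Without TGFb Pcdhga1 rose (0.35 ± 0.09, limma adjusted p = 0.01). Pcdha8, Pcdha9, Pcdha12, Pcdhga5, Pcdhga9, Pcdhga10 and Pcdhgb1 were not called, with values from -0.36 to 0.23. Of 11 protocadherin genes outside the clusters 8 rose and 1 fell without TGFb, with rises of Pcdh9 (1.10 ± 0.07), Pcdh15 (1.11 ± 0.13) and Pcdh10 (0.96 ± 0.05) and a fall of Pcdh8 (-1.06 ± 0.10). That family too was past the threshold only with the preset correlation (adjusted p = 0.00791, but adjusted p = 0.934 with an estimated correlation).

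Genes that host small nucleolar RNAs (Snhg) were mostly lower in knockdown cells without TGFb: 7 of 10 fell and 1 rose, with Snhg16 at -0.72 ± 0.05, Snhg10 at -0.63 ± 0.06 and Snhg11 rising by 0.79 ± 0.22 (adjusted p = 0.024, but adjusted p = 0.934 with an estimated correlation). The ribosomal protein genes, many of which also host such RNAs, had means of -0.18 for the Rpl family (0 up and 20 down of 48) and -0.19 for the Rps family (0 up and 15 down of 44). For the Rpl family the mean shrank to -0.05 after quantile normalization, with 4 down, and for the Rps family to -0.10, with 5 down and 1 up, while the authors' values gave -0.06 with 2 down and -0.10 with 5 down. Median scaling left the means at -0.17 and -0.18, with 2 and 6 down. Neither family was past the threshold with an estimated correlation. Chemokine genes were higher without TGFb, with 6 of 14 up and 0 down, led by Ccl12 (1.47 ± 0.14), Ccl21a (1.03 ± 0.13) and Ccl7 (1.01 ± 0.08) (adjusted p = 0.032, but adjusted p = 0.934 with an estimated correlation).

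Of the 21 genes whose TGFb response differed between the lines, 17 differed between the lines without TGFb and 14 with it, and for 14 the difference was larger without TGFb. Mgp was higher in knockdown cells by 3.23 without TGFb (1.17 with normexp background correction) and by 0.88 with TGFb, and Gas1 was lower by 0.73 (adjusted p = 3.0e-05) and had a value of 0.20 (adjusted p = 0.073) with TGFb. Dclk3, by contrast, differed between knockdown and control cells by -0.01 (adjusted p = 0.96) without TGFb and was lower in knockdown cells by 1.47 with TGFb. These counts and values share arrays with the difference of responses, so that they are not independent evidence on it.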
